A study of Mus musculus with 16 samples.

How the data were processed

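RNA from a 3 mm slice of the middle of the kidney of 16 female C57BL/6 mice aged 2 to 3 months was sequenced as 1 Illumina library per animal, per the labels' protocols. The mice were labelled wild type or IRR(-/-), a knockout of Insrr, and drank water or water with 250 mM sodium bicarbonate at pH 8.5 for 7 days. All fasted for 12 h before the kidneys were taken. The 2 genotypes and 2 drinks made 4 groups of 4 animals, which were taken from the genotype and treatment labels. The labels give no sequencing batch, litter or date.

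The deposited values are RPKM per gene, 1 column per library, in 1 table made by the authors. Salmon 1.5.2 and edgeR 3.34.0 are named in the submitters' processing notes, without the step each was used for. These notes name the builds GRCm39 and mm10 with no role, so the annotation behind the values is not given in the sources used here. All gene IDs in the table matched a symbol in the GENCODE M21 annotation of GRCm38, which was used for symbols, positions, transcript lengths and GC content. Whole reads could not be recovered from the values, so the depth of each library is unknown and no interval for counting error is given. A value of exactly 0 can be a failed estimate, so such genes are described as listed at 0, with the values of the libraries.

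Genes with an RPKM of at least 0.5 in at least 4 of the 16 libraries were tested, which left 12943 genes and set aside 487. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.1), with the trended and robust empirical Bayes variance, in 1 fit of the 4 group means over all 16 libraries with 12 residual degrees of freedom. Each adjusted p is a Benjamini-Hochberg value over all genes tested within a comparison, with a threshold of 0.05, and all tests were two-sided. Log2 differences are on the log2(RPKM + 0.1) scale and so understate the change of low genes. The 4 comparisons of group pairs were bicarbonate minus water in each genotype and knockout minus wild type on each drink. The interaction is the knockout response to bicarbonate minus the wild-type response. A contrast that averages the responses of both genotypes was chosen after seeing the data and appears in the closing section.

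The test, the groups, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 29 gene lists covered type B intercalated cells, type A intercalated cells, intercalated cell V-ATPase and shared genes, proximal bicarbonate reabsorption, ammoniagenesis and gluconeogenesis, thick limb and distal sodium chloride transport, mineralocorticoid and glucocorticoid response, handling of calcium, magnesium and phosphate, collecting duct water and medullary osmolytes, renin and angiotensin, insulin and IGF signalling, genes near Insrr on chromosome 3, fasting and PPAR alpha targets, cholesterol synthesis, circadian clock, immediate early genes, heat shock, interferon response, tubule injury and cell cycle. The other lists held markers of the proximal tubule, podocytes, endothelium, stroma and matrix, immune cells, haemoglobin of blood cells, urothelium, the adrenal gland and adipose tissue. Of the 321 listed genes, 295 were in the table and 290 were tested. Lists with at least 3 tested members were run, which left 28, and the adrenal list had too few. Each was tested with camera in limma at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it.

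The rule named Insrr, then the 8 highest and 8 lowest log2 differences per pairwise comparison among genes past the threshold with no overlap between the groups, a mean RPKM of at least 1 in the higher group and a regular symbol. It added up to 3 members per list with the smallest p past the threshold, the 10 smallest p where fewer than 10 genes passed, all tested members of the 2 lists of type A and type B intercalated cells, and the 5 smallest p of each sign for the interaction. The text gives values for a part of these genes and counts for the rest, and some genes within these counts are not reported here. Among the genes that differed between genotypes, values are mainly given for those whose call held with each library left out in turn.

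Before the comparisons were tested on the real values, the procedure was tested on simulated values with 100 genes changed per fold size. The simulated values took the means and residual SDs of the real genes from a fit of the 4 groups. At a 2-fold change it recovered 71% of them for bicarbonate in wild type, 79% for bicarbonate in the knockout, 66% for genotype on water, 67% for genotype on bicarbonate and 56% for the interaction. At a 1.5-fold change it recovered 52%, 45%, 43%, 39% and 21% in that order. Both fold sizes were changed in the same simulated values, so false calls were counted once per comparison, and numbered 5, 14, 3, 5 and 1. No library pair within a group held identical values, and the smallest median absolute log2 difference between 2 libraries of a group was 0.15.

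The alternatives fixed with the design were pseudocounts of 0.01 and 1, no filter or a mean RPKM of at least 1, scaling by median-of-ratios size factors or quantile normalization, a variance without trend or robust fitting, array weights, only the groups compared, the replicate number as a block, an adjusted p threshold of 0.1, and each library left out. Removal of a trend on transcript length and GC content, fitted per library with splines of 5 degrees of freedom, a restriction to genes above 0 in every library, further list alternatives and all alternatives of the averaged contrast and of the agreement between comparisons were added after seeing the data.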

Results

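The data were RPKM values of genes in kidney slices of 16 mice, with 4 wild-type mice on water, 4 wild-type mice on bicarbonate, 4 IRR knockout mice on water and 4 IRR knockout mice on bicarbonate. IRR, the product of Insrr, is a receptor tyrosine kinase of the insulin receptor family that responds to alkaline pH outside the cell. The series asks how the kidney answers an alkali load with and without this receptor. The median RPKM of a library lay between 8.44 and 8.92. The summed RPKM differed between genotypes, at 1.54e+06 ± 55556 in wild type on water, 1.44e+06 ± 77374 in wild type on bicarbonate, 2.84e+06 ± 92934 in the knockout on water and 2.62e+06 ± 143107 in the knockout on bicarbonate (SD, n = 4 each). The 13 mitochondrially encoded genes made up 72.7 ± 1.63%, 70.9 ± 0.890%, 84.1 ± 0.671% and 83.5 ± 0.742% of these sums in the same order. The first principal component held 25.4% of the variance and separated all 8 wild-type libraries, at -24.2 or below, from all 8 knockout libraries, at 21.4 or above. Wild-type bicarbonate replicate 3 stood apart on the second component, at -50.8.

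Insrr was lower in the knockout libraries but was not absent from them. Its level was 5.93 ± 0.824 RPKM in wild type on water and 5.13 ± 0.972 RPKM in wild type on bicarbonate, against 3.62 ± 0.343 and 3.58 ± 0.181 RPKM in the knockout groups (SD, n = 4 each). The 8 wild-type libraries lay between 4.20 and 6.73 RPKM and the 8 knockout libraries between 3.31 and 4.11 RPKM, so no library overlapped with the other genotype. The log2 difference was -0.69 ± 0.13 (SE, limma adjusted p = 0.00180) on water and -0.49 ± 0.13 (adjusted p = 0.0182) on bicarbonate. The call on bicarbonate was lost without wild-type bicarbonate replicate 4, at a log2 difference of -0.37, and without IRR knockout bicarbonate replicate 2, at -0.46. The part of the gene that the knockout removes is not given in the labels, so the remaining values do not check whether the protein was lost. Insrr starts at position 87796951 of chromosome 3 in GRCm38.

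**Figure D1:**
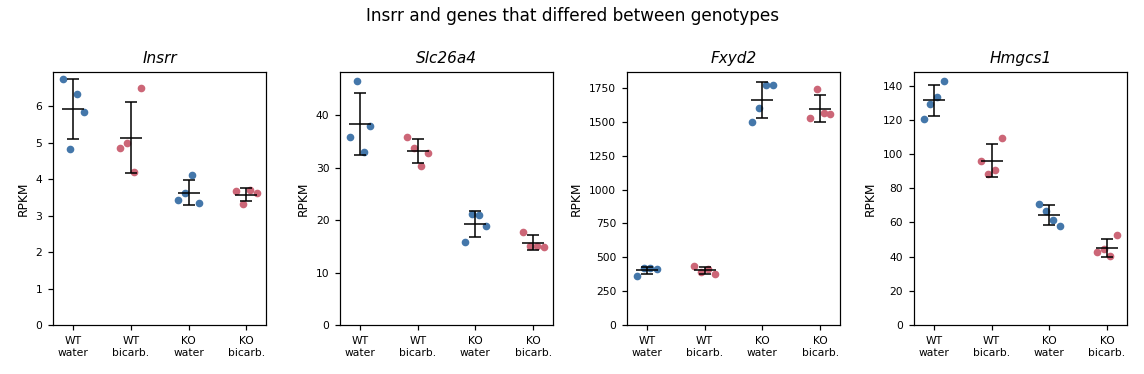
RPKM (vertical axes, from 0) of Insrr, Slc26a4, Fxyd2 and Hmgcs1 in the 4 groups (horizontal axes), with a point per mouse and the mean with its SD as a bar (n = 4). Fxyd2 had a mean of 404 RPKM in wild type on water and 1660.5 RPKM in the knockout on water, and Insrr had means of 5.93 and 3.62 RPKM in these groups.

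The response of the normal kidney to the alkali load was read from wild-type mice on bicarbonate and on water. The transporter genes Slc13a3, Slc6a20b and Slc22a8 were among 13 genes lower after bicarbonate. Slc13a3, the sodium-dependent dicarboxylate transporter, went from 245 ± 29.2 to 165 ± 10.1 RPKM (SD, n = 4 each), a log2 change of -0.57 ± 0.08 (SE, adjusted p = 0.0181). Slc6a20b, an amino acid transporter, fell by 0.58 on the log2 scale, Slc22a8, the organic anion transporter OAT3, fell by 0.30, and Enpp6, a choline phosphodiesterase, fell by 0.56. Wdr72 fell by 1.17, and the genes Afm, Plscr2 and Ly6a by 0.64, 0.45 and 0.42. On the higher side, Acp2, lysosomal acid phosphatase, went from 4.11 ± 1.03 to 33.9 ± 6.98 RPKM (log2 change 3.03 ± 0.37, adjusted p = 0.00592), and Plcxd1, Rasa3, Arl4d and the splicing regulator Ptbp1 rose by 1.399, 0.80, 0.64 and 0.47. In total 5 genes rose and 13 fell of 12943 tested, with 1549 genes at an unadjusted p under 0.05. The groups did not overlap for 758 genes (5.86%), against 2.86% by chance.

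These calls depended on single libraries and on settings. The count was 5 with only the groups compared and 10 with the length and GC trend removed. It fell with the replicate number as a block and rose with quantile normalization, as given in the part on processing. The count was 4, 6 and 9 without wild-type water replicates 1, 2 and 3, and 5, 2, 5 and 82 without wild-type bicarbonate replicates 1, 2, 3 and 4. Of the 14 called genes that the rule picked in this comparison, Acp2 kept its call with each library left out. For the other 13, calls lost without wild-type water replicates 1, 2, 3 and 4 numbered 12, 11, 9 and 7, with adjusted p from 0.0554 to 0.136. Without wild-type bicarbonate replicates 1, 2 and 3 they numbered 12, 13 and 10, with adjusted p from 0.0559 to 0.134. With all libraries, 13 lost their calls with only the groups compared (adjusted p from 0.170 to 0.288). Another 13 losses came with the replicate number as a block (0.0604 to 0.0824), though these numbers did not pair the animals. Calls were lost by 7 with the length and GC trend removed (0.0627 to 0.0843) and 5 without trend or robust fitting of the variance (0.0533 to 0.0896). They were lost by 4 with median-of-ratios scaling, 4 with array weights and 1 with quantile normalization. Slc13a3 and Ly6a lost theirs without only 2 libraries each, which for Slc13a3 were wild-type bicarbonate replicates 1 (log2 change -0.53, adjusted p = 0.0559) and 2 (-0.59, adjusted p = 0.0701), and for Ly6a wild-type water replicate 1 (-0.38, adjusted p = 0.0566) and wild-type bicarbonate replicate 2 (-0.40, adjusted p = 0.0708).

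Among the gene lists, proximal tubule markers were lower in wild type after bicarbonate, with 2 of 16 (Slc13a3 and Slc22a8) lower past the threshold, 0 higher, 14 not passing and a median log2 change of -0.28 (camera adjusted p = 1.73e-05). Adjusted over the list alone, 4 fell. The call was lost with an estimated correlation, at adjusted p = 0.124 with an estimated correlation. Kap, a protein of proximal tubule cells, stood at 742 RPKM in wild-type bicarbonate replicate 3 against 7148 to 9256 RPKM in the other 3 libraries of that group, and the list was still called without that library. Fasting and PPAR alpha targets, which act in fatty acid oxidation and ketone synthesis, had positive changes in 10 of 10 members with a median of 0.80 (adjusted p = 1.73e-05, adjusted p = 0.415 with an estimated correlation). None passed over all genes, 7 had an unadjusted p under 0.05, and 4 rose adjusted over the list alone. An example chosen after its values were seen is Angptl4 at 0.80 ± 0.28 (adjusted p = 0.257 over all genes).

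Interferon response genes had negative changes in 11 of 11 members with a median of -0.31 (adjusted p = 0.000596, adjusted p = 0.172 with an estimated correlation). None passed over all genes, 3 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone. The renin and angiotensin list was lower, with 1 of 7 past the threshold and 3 adjusted over the list alone (adjusted p = 0.0457, adjusted p = 0.172 with an estimated correlation). It was not called without wild-type water replicates 1, 3 and 4 (adjusted p = 0.0708, 0.0743 and 0.0625) or wild-type bicarbonate replicates 1 and 3 (adjusted p = 0.118 and 0.0531). With quantile normalization its adjusted p was 0.0710 and with the length and GC trend removed 0.0692, and over all its alternatives it was called in 6 of 14. The other 23 lists of the 28 tested were not called, and fry called 3 lists. Without wild-type water replicate 1 camera called 3 lists. Median, mean and test direction differed in sign for proximal bicarbonate reabsorption, for calcium, magnesium and phosphate handling and for podocyte markers.

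Intercalated cells secrete acid (type A) or bicarbonate (type B). In wild type, the type A list was higher after bicarbonate (adjusted p = 0.0105, adjusted p = 0.534 with an estimated correlation), with positive changes in 5 of 5 members and a median of 0.44. None passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list was not called without wild-type water replicate 1 (adjusted p = 0.0708) or wild-type bicarbonate replicate 3 (adjusted p = 0.0692). The log2 changes were 0.63 for the anion exchanger Slc4a1, 0.12 for Kit, 0.45 for Aqp6, 0.43 for Dmrt2 and 0.44 for Adgrf5, with adjusted p from 0.250 to 0.887. The type B list had 0 of 5 members past the threshold, with 0 at an unadjusted p under 0.05. Slc26a4, the chloride-bicarbonate exchanger pendrin, had a log2 change of -0.20, Insrr -0.21, Hmx2 0.06, Slc4a8 0.28 and Oxgr1 -0.02, with adjusted p from 0.519 to 0.982. The signs of the small values for Hmx2, Oxgr1 and Kit turned under some settings.

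The same drinks were compared in the IRR(-/-) mice. In the knockout, Slc13a3 went from 299 ± 20.3 to 188 ± 9.56 RPKM (SD, n = 4 each), a log2 change of -0.67 ± 0.08 (SE, adjusted p = 0.00503). Spc25, a kinetochore protein, went from 55.8 ± 3.90 to 32.6 ± 1.18 RPKM (log2 change -0.77 ± 0.11, adjusted p = 0.0258). Sh3bp5l went from 5.29 ± 0.140 to 13.4 ± 3.09 RPKM (log2 change 1.30 ± 0.14, adjusted p = 0.00227). These 3 genes, 1 higher and 2 lower, were the ones past the threshold, with 1034 at an unadjusted p under 0.05. Groups did not overlap for 732 genes (5.66%), against 2.86% by chance. The next smallest p did not pass and belonged to Enpp6 (-0.53, adjusted p = 0.105), the organic anion transporter Slc22a6 (-0.53, adjusted p = 0.134), Hmgcs1 of cholesterol synthesis (-0.52), carbonic anhydrase Car2 (-0.37), Knstrn (-1.48), Mrpl28 (-0.80) and Naa38 (-0.53), the last 5 with adjusted p from 0.141 to 0.158. With the length and GC trend removed, Enpp6 and Slc22a6 passed, at adjusted p = 0.0310 and 0.0484. Spc25 lost its call without each library of the 2 groups apart from IRR knockout water replicate 4, at adjusted p from 0.0577 to 0.162. It also lost it with the length and GC trend removed (0.0639), without trend or robust fitting of the variance (0.0617) and with the replicate number as a block (0.0716). Sh3bp5l lost its call with only the groups compared, at adjusted p = 0.0690.

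**Figure D2:**
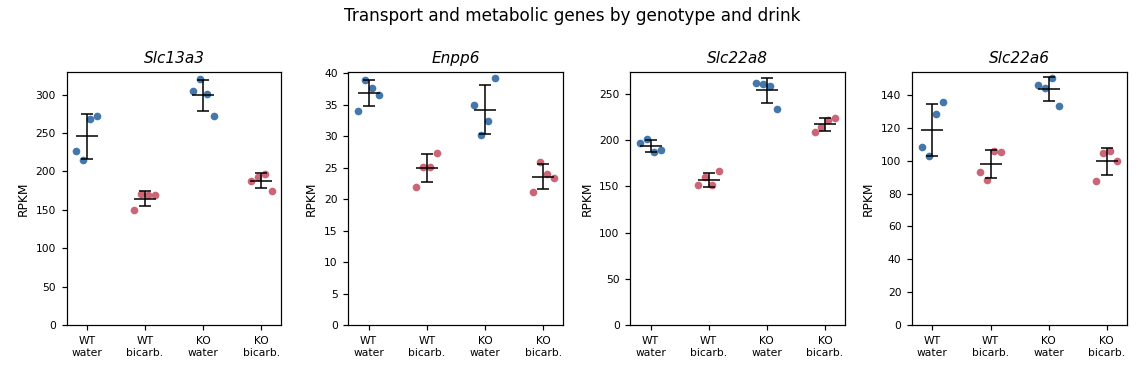
RPKM (vertical axes, from 0) of Slc13a3, Enpp6, Slc22a8 and Slc22a6 in the 4 groups (horizontal axes), with a point per mouse and the mean with its SD as a bar (n = 4). Slc13a3 had means of 245 and 165 RPKM in wild type on water and on bicarbonate, and of 299 and 188 RPKM in the knockout.

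In the knockout, 6 lists were called after bicarbonate. Haemoglobin genes of blood cells were lower, with negative changes in 5 of 5 members and a median of -1.14 (adjusted p = 0.000168, adjusted p = 0.396 with an estimated correlation). None passed over all genes, 4 had an unadjusted p under 0.05, and 2 fell adjusted over the list alone, chosen after their values were seen, Hbb-bt at -1.76 and Hba-a2 at -1.30. The list of V-ATPase and shared genes of intercalated cells was lower, with negative changes in 14 of 17 members and a median of -0.14 (adjusted p = 0.00113, adjusted p = 0.227 with an estimated correlation). None passed, 6 had an unadjusted p under 0.05, and 1 (Car2) fell adjusted over the list alone. Proximal tubule markers were lower with 1 of 16 past the threshold and 3 adjusted over the list alone, 8 members negative and a median of -0.02 (adjusted p = 0.0331, adjusted p = 0.396 with an estimated correlation). With quantile normalization this median was 0.03 and the list was not called (adjusted p = 0.460). The lists of ammoniagenesis and gluconeogenesis (median -0.20, adjusted p = 0.0386, adjusted p = 0.644 with an estimated correlation) and cell cycle (median -0.34, 9 of 9 negative, adjusted p = 0.0331, adjusted p = 0.396 with an estimated correlation) were lower. Insulin and IGF signalling was higher (median 0.11, 15 of 16 positive, adjusted p = 0.0331, adjusted p = 0.227 with an estimated correlation). None of the members of these 3 lists passed over all genes, and 1, 0 and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 0, 0 and 1 passed.

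Calls of 4 of these lists were lost with single libraries left out. Proximal tubule markers lost theirs without IRR knockout water replicates 3 and 4 (adjusted p = 0.139 and 0.172) and bicarbonate replicate 3 (0.114). The cell cycle list lost it without the same 3 libraries (0.0615, 0.172 and 0.202), and also with the length and GC trend removed (0.0695). Ammoniagenesis and gluconeogenesis lost it without IRR knockout water replicates 2 and 3 (0.0707 and 0.231) and bicarbonate replicates 2, 3 and 4 (0.119, 0.114 and 0.0565), and with quantile normalization (0.394). Insulin and IGF signalling lost it without IRR knockout water replicates 1, 2 and 3 (0.0622, 0.0603 and 0.0910) and bicarbonate replicates 1 and 2 (0.0754 and 0.0571), and with the length and GC trend removed (0.189). The number of lists called was 2 without water replicate 3 and 3 without bicarbonate replicate 3 of the knockout. The other 22 lists were not called and fry called 0, and median, mean and test direction differed in sign for proximal bicarbonate reabsorption, the corticoid response and cholesterol synthesis.

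Both lists of intercalated cell types had 0 members past the threshold in the knockout, with 2 type B members and 0 type A members at an unadjusted p under 0.05, and 1 type B member rose adjusted over the list alone. Log2 changes of the type B members were -0.28 for Slc26a4, -0.01 for Insrr, -0.28 for Hmx2, 0.75 for Slc4a8 and -0.28 for Oxgr1, with adjusted p from 0.301 to 0.995. Those of the type A members were 0.16 for Slc4a1, -0.18 for Kit, -0.28 for Aqp6, -0.11 for Dmrt2 and 0.03 for Adgrf5, with adjusted p from 0.802 to 0.992. The signs for Insrr, Dmrt2 and Adgrf5 turned under some settings.

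The baseline effect of the genotype was read from knockout and wild-type mice on water. Pendrin, encoded by Slc26a4, was lower in the knockout, at 19.3 ± 2.51 RPKM against 38.4 ± 5.85 RPKM in wild type (SD, n = 4 each), a log2 difference of -0.99 ± 0.11 (SE, adjusted p = 2.53e-05). Fxyd2, the gamma subunit of the sodium-potassium ATPase, was higher, at 1660.5 ± 133 against 404 ± 27.4 RPKM (log2 difference 2.04 ± 0.07, adjusted p = 1.10e-10). Hmgcs1, an enzyme of cholesterol synthesis, was lower, at 64.2 ± 5.75 against 131 ± 9.18 RPKM (log2 difference -1.03 ± 0.09, adjusted p = 3.14e-06). H2-Ab1, an antigen-presenting class II chain, was higher by 1.26 ± 0.16 (adjusted p = 6.63e-05). In total 1303 genes were higher and 1530 lower in the knockout (21.9% of those tested, 46.0% of them higher), and 336 of these differed by over 2-fold. Groups did not overlap for 3075 genes (23.8%), against 2.86% by chance. Share called and direction depended on the length of the longest transcript. The median log2 difference was 0.75 for the 34 genes of up to 500 nt (55.9% called). It was 0.34 at 501 to 1000 nt (47.6% called). In the 3 bins of longer genes it lay between -0.07 and -0.01 (16.8% to 25.4% called). No batch is given in the labels, so a batch that follows the genotype cannot be told apart from it.

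The 13 mitochondrially encoded genes, chosen after their values were seen, were all higher in the knockout on both drinks, by log2 differences from 0.55 (mt-Co3) to 2.76 (mt-Nd3) on water with a median of 1.11, and with a median of 1.12 on bicarbonate, but not with quantile normalization, where 2 were higher and 1 lower on water and 2 higher and 2 lower on bicarbonate. Most of them hold the highest values of a library, which that method sets equal across libraries. With the length and GC trend removed, 11 of 13 were higher on each drink, and mt-Nd4l was lower on water (-0.57, adjusted p = 0.0118). The gene mt-Atp8 alone took 45.0 ± 1.403% of the summed RPKM in wild type and 56.3 ± 1.25% in the knockout on water (SD, n = 4 each). This is a share of RPKM and not of reads, since RPKM divides by a transcript length that is not given here and mt-Atp8 is very short. Summed RPKM of the other, nuclear genes was 419603 ± 15108 in wild type and 449373 ± 12102 in the knockout on water.

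By list, sodium chloride transport of the thick limb and distal tubule had 5 of 17 members higher, 1 lower and 11 not passing on water, with Wnk4, a kinase of distal salt transport, at 0.86 and uromodulin, Umod, chosen after its values were seen, lower at -0.54. Of 5 type B members, 2 were lower (Slc26a4 and Insrr), and Hmx2 (-0.45), Slc4a8 (0.11) and Oxgr1 (0.26) did not pass. Insrr is the gene knocked out, so its lower value does not count as a sign of type B cells. Of 5 type A members, Aqp6 (1.01 ± 0.22, adjusted p = 0.00434) and Adgrf5 (0.74 ± 0.21, adjusted p = 0.0182) were higher, while Kit (0.45), Dmrt2 (0.34) and Slc4a1 (0.02) did not pass. The call of Adgrf5 was lost without wild-type water replicates 1 and 2 (both at a log2 difference of 0.59, adjusted p = 0.0584 and 0.0632) and without IRR knockout water replicate 4 (0.65, adjusted p = 0.0544). It was also lost with only the groups compared (adjusted p = 0.0652). The signs for Slc4a1 and Slc4a8 turned under some settings. Proximal tubule markers had 4 of 16 higher and 1 lower, with Slc22a8 at 0.39 and the glucose transporter Slc5a2 at -0.44. The V-ATPase and shared list had 1 of 17 higher and 2 lower, with Atp6ap2 at -0.41 and Atp6v1a at -0.38. The renin and angiotensin list had 4 of 7 lower. Collecting duct water and osmolyte genes had 1 of 11 higher, the taurine transporter Slc6a6 at 0.76, and 3 lower, among them the water channel Aqp4 at -3.71. Calcium, magnesium and phosphate handling had 3 of 18 higher, such as the calcium pump Atp2b4 at 1.12, and 2 lower. Ammoniagenesis and gluconeogenesis had 1 of 11 higher and 2 lower, among them fructose bisphosphatase Fbp1 at -0.49. Proximal bicarbonate reabsorption had 1 of 9 higher and 1 lower, the anion exchanger Slc4a2 at -0.70.

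Of the signalling and stress lists on water, the corticoid response had 2 of 10 higher and 1 lower, the glucocorticoid receptor Nr3c1 at -0.53, and the circadian clock 3 of 16 higher, among them Per1 at 0.55 and Hlf at 0.60. Interferon response had 2 of 11 lower, among them Irf7 at -1.74, and cholesterol synthesis 2 of 12 lower, Hmgcs1 and Fdps at -0.997. Tubule injury had 1 of 10 higher and 3 lower, with clusterin, Clu, at -0.65 and the fibrinogen chain Fgg at -2.10. Heat shock had 1 of 9 higher, Hspe1 at 0.62, and 2 lower, among them its partner chaperonin Hspd1 at -0.46. Immune cell markers had 2 of 9 higher, H2-Ab1 and Cd74 at 0.59. Genes near Insrr had 3 of 16 higher, such as Naxe at 0.54 and Pear1 at 0.83, and 2 lower, among them Cct3 at -0.36, with Insrr itself in another list. Immediate early genes had 1 of 10 lower (Dusp1 at -0.67), and insulin and IGF signalling (16 tested), endothelium (7) and stroma (11) each 1 lower, counts that became 0 in 6, 1 and 2 of 8 fits with single libraries left out. In such fits the 4 genes lower of the renin list and the 4 higher of the proximal tubule fell to as few as 1. Fasting and PPAR alpha targets had 0 of 10 past the threshold with 4 at an unadjusted p under 0.05, and the lists of cell cycle (9), podocytes (7), haemoglobin (5), urothelium (5) and adipose tissue (5) had 0 past it and 0 at an unadjusted p under 0.05. Adjusted over the list alone, the counts higher and lower moved to 2 and 1 for proximal bicarbonate reabsorption, 2 and 2 for ammoniagenesis, 4 and 3 for calcium handling, 1 and 5 for heat shock, 4 and 2 for the proximal tubule, and 0 and 0 for insulin signalling and for stroma, and were the same for the rest. Camera called 0 of 28 lists, with 6 at an unadjusted p under 0.05, and fry called 6. Median, mean and test direction differed in sign for the lists of ammoniagenesis, corticoid response, calcium handling, proximal tubule, immune cells and urothelium.

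Some genes were listed at or near 0 throughout one genotype. Idh3a, a subunit of isocitrate dehydrogenase that cells use in the citric acid cycle, was listed at 0 in all 8 wild-type libraries and at 14.7 to 33.5 RPKM in the 8 knockout libraries. Morn2 was listed at 0 in all 8 knockout libraries and at 13.0 to 27.0 RPKM in wild type, and Fam133b likewise, at 6.15 to 10.6 RPKM in wild type. Krcc1 lay at 0 to 2.86 RPKM in wild type and at 27.3 to 46.8 RPKM in the knockout. Values of Hsd3b4 (0 to 20.8 against 115 to 374 RPKM), Eno1b (0 to 4.28 against 155 to 224 RPKM), Hist2h2aa1 (13.8 to 29.0 against 0 to 5.13 RPKM), Hist1h2ap (2.50 to 8.34 against 0 to 2.33 RPKM) and Rsc1a1 (1.21 to 6.89 RPKM against a listed 0), given for wild type and then the knockout, are uncertain. Each matches a near-identical transcript of another gene with which reads can be shared. For Rsc1a1, with 100% of its exonic bases overlapped, that can be the overlapping gene and not a separate copy. In all, 40 genes differed by over 8-fold on water, and 53 of the genes called had at least 1 library at 0.

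On bicarbonate, the genotypes were compared to see the effect of the knockout under the alkali load. Slc26a4 was lower in the knockout, at 15.7 ± 1.37 against 33.2 ± 2.23 RPKM (SD, n = 4 each), a log2 difference of -1.07 ± 0.11 (SE, adjusted p = 1.78e-05). Fxyd2 was higher by 1.98 ± 0.07 (adjusted p = 1.68e-10) and Hmgcs1 lower, at -1.10 ± 0.09 (adjusted p = 2.71e-06). The fibrinogen chains Fgb and Fgg were lower, at -3.09 ± 0.45 and -3.46 ± 0.43. In total 1169 genes were higher and 1212 lower (18.4%, 49.1% of them higher), of which 222 by over 2-fold and 33 by over 8-fold. Groups did not overlap for 2955 genes (22.8%), against 2.86% by chance. As on water, short transcripts were called more often and were higher in the knockout. The median log2 difference was 0.39 up to 500 nt (38.2% called) and 0.20 at 501 to 1000 nt (38.0% called). For longer genes it lay between -0.06 and 0.06 (15.1% to 22.7% called). Between the 2 drinks, 778 genes were higher and 766 lower in the knockout on both, where independent lists of these sizes would share 118 and 143, and 2 were opposite. Across 12943 genes, which are not independent replicates, the genotype differences on the 2 drinks correlated with a Pearson r of 0.625 and a Spearman rho of 0.579.

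The list of thick limb and distal sodium chloride transport was higher in the knockout on bicarbonate (adjusted p = 0.0186, adjusted p = 0.347 with an estimated correlation), with 5 of 17 members higher and 1 lower over all genes, and 6 higher and 1 lower adjusted over the list alone. Wnk4 stood at 0.74, Klhl3 at 0.39 and Umod at -0.41, Klhl3 and Umod being chosen after their values were seen. The list was not called without wild-type bicarbonate replicate 1 (adjusted p = 0.0596). The number of lists called was 0 without that library, 4 without wild-type bicarbonate replicates 2 and 4 each, 2 without its replicate 3, and 2 and 4 without IRR knockout bicarbonate replicates 1 and 4. It was 3 with quantile normalization and with median-of-ratios scaling and 2 with the length and GC trend removed. The other 27 lists were not called, and fry called 4 lists.

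Type B members were 3 of 5 lower on bicarbonate (Slc26a4, Hmx2 and the knocked-out gene Insrr itself) and 1 higher (Slc4a8). Hmx2 stood at -0.79 ± 0.22 (adjusted p = 0.0188), and lost its call without wild-type bicarbonate replicate 1 (-0.64) and IRR knockout bicarbonate replicates 3 (-0.66) and 4 (-0.71), and with only the groups compared (adjusted p = 0.0703). Slc4a8, a bicarbonate transporter, stood at 0.58 ± 0.19 (adjusted p = 0.0402), and kept its call with wild-type bicarbonate replicate 4 left out but lost it without each other library of these groups, at adjusted p from 0.0513 to 0.116, and with the length and GC trend removed, at adjusted p = 0.124. Oxgr1 (0.00) did not pass. Type A members had 0 of 5 past the threshold, with Slc4a1 at -0.45, Kit at 0.14, Aqp6 at 0.27, Dmrt2 at -0.20 and Adgrf5 at 0.33 and adjusted p from 0.172 to 0.711. Kit and Oxgr1 changed sign under some settings. Insulin and IGF signalling had 3 of 16 higher, among them the insulin receptor substrate Irs2 at 0.98 and the insulin receptor Insr at 0.38, and 1 lower. Tubule injury had 3 of 10 lower and haemoglobin 2 of 5 lower, with Hba-a2 at -1.89. With single libraries left out, haemoglobin had 1 lower in 7 of 8 fits and insulin signalling 0 lower in 6 of 8, while tubule injury had 3 in each. Proximal tubule markers had 2 of 16 higher, Slc22a8 at 0.47 and Hnf4a at 0.26, and 1 lower, Slc5a2 at -0.52. Adjusted over the list alone, haemoglobin had 4 lower, insulin signalling 4 higher and the proximal tubule 3 higher. Median, mean and test direction differed in sign for proximal bicarbonate reabsorption, calcium handling, genes near Insrr, interferon response, podocytes and immune cells.

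Whether the 2 genotypes answered the alkali load differently was tested by the interaction. Sh3bp5l rose by 1.35 ± 0.20 (SE) more in the knockout on the log2 scale (adjusted p = 0.0471). Gm5096, listed at 0 in 12 libraries and present in wild type on water alone, also passed (adjusted p = 0.000697) and lost its call with a pseudocount of 0.01 (adjusted p = 0.422). These were 2 of 12943 genes, both positive, with 543 positive and 517 negative at an unadjusted p under 0.05. Next on the positive side were Ikzf2 (0.89, adjusted p = 0.137), Zfp451 (0.97) and glycogen synthase Gys2 (1.48), and on the negative side Knstrn (-2.55, adjusted p = 0.0520), Acp2 (-3.18, adjusted p = 0.0844), Bub3 (-1.43), Cbr4 (-0.62) and Srrd (-1.16), none of which passed. The call of Sh3bp5l was lost without any 1 of 13 libraries, at adjusted p from 0.0570 to 0.137, and held without wild-type bicarbonate replicates 1 and 4 and IRR knockout bicarbonate replicate 3. It was also lost with pseudocounts of 0.01 and 1 (0.0876 and 0.0541), a mean RPKM of at least 1 (0.0853) and array weights (0.0818). With the replicate number as a block it was lost as well (0.0924), while Acp2 passed (0.0347). The count was 4 without wild-type bicarbonate replicate 1 and 5 without its replicate 4. It was 1 without wild-type water replicates 1, 2 and 4, wild-type bicarbonate replicates 2 and 3, IRR knockout water replicates 1, 2 and 3, and IRR knockout bicarbonate replicate 4. Single libraries also brought calls, for Acp2 without IRR knockout water replicate 4 (adjusted p = 0.0440), Gys2 and Zfp451 without IRR knockout bicarbonate replicate 1 (0.0313 and 0.0240), Ikzf2 without wild-type bicarbonate replicate 4 (0.0442), Knstrn without IRR knockout bicarbonate replicate 2 (0.0174) and Srrd without IRR knockout bicarbonate replicate 3 (0.0102). Knstrn also passed with quantile normalization (0.0498), median-of-ratios scaling (0.0478), the length and GC trend removed (0.0340) and 3 further settings. Slc13a3 had an interaction of -0.10 ± 0.12 (adjusted p = 0.844).

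By camera, 8 lists differed between the responses and 0 with an estimated correlation, at adjusted p = 0.313 with an estimated correlation for 7 of them and 0.349 for fasting targets. Fry called 0. Haemoglobin (median -1.69, 5 of 5 negative, adjusted p = 0.000758), fasting and PPAR alpha targets (median -0.72, 9 of 10 negative, adjusted p = 0.00115), type A intercalated cells (median -0.47, 5 of 5 negative, adjusted p = 0.0144), cell cycle (median -0.59, 8 of 9 negative, adjusted p = 0.0144), tubule injury (median -1.05, 8 of 10 negative, adjusted p = 0.0167) and V-ATPase and shared genes (median -0.12, 13 of 17 negative, adjusted p = 0.0179) had lower responses in the knockout. Interferon response (median 0.44, 9 of 11 positive, adjusted p = 0.0217) and insulin and IGF signalling (median 0.15, 13 of 16 positive, adjusted p = 0.0397) had higher ones. Adjusted over the list alone, 4 haemoglobin genes were lower, 1 interferon gene and 1 insulin signalling gene were higher, and 0 members of the other 5 lists passed. The V-ATPase list was not called without wild-type water replicate 1 (adjusted p = 0.0752) or with quantile normalization (0.0772), and cell cycle not without wild-type water replicate 3 (0.0512). Interferon response was not called without wild-type water replicates 1 (0.0903) and 2 (0.0611), IRR knockout water replicates 2 (0.0765) and 4 (0.0535) and IRR knockout bicarbonate replicate 3 (0.0504). Insulin and IGF signalling was called in 10 of 22 alternatives. Its call was lost without wild-type water replicates 3 (0.0815) and 4 (0.0677), wild-type bicarbonate replicates 1 (0.0731) and 4 (0.0700), IRR knockout water replicates 1 (0.0641), 2 (0.0765) and 3 (0.0966), and IRR knockout bicarbonate replicates 1 (0.0779), 2 (0.0504) and 4 (0.0593), and with the length and GC trend removed (0.207).

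Across genes, the bicarbonate responses of the 2 genotypes correlated with a Pearson r of 0.0224 and a Spearman rho of 0.0626, and these comparisons share no library. Of the 18 genes called in wild type, 16 had the same sign in the knockout. Slc13a3 was the 1 gene that fell in both, against 0.00201 expected from independent lists. The wild-type response to bicarbonate and the genotype difference on water share the wild-type water libraries. Their r was 0.387 (rho 0.384), against 0.498 in 100 simulations with no effect, and their covariance was 0.0775 against a simulated 0.0504, a difference of 0.0270. With the wild-type water libraries split between the comparisons in 6 ways, r was 0.101 on average (0.0687 to 0.143) and the covariance 0.0258.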

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

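All tests of explanations in this part were chosen only after the result was seen, except the counts of other splits of the libraries for planned comparisons. In the split of the libraries by genotype, 2833 genes differed on water and 2381 on bicarbonate, against at most 2 and 1 in the other of 35 splits each, and chance can be excluded for both. For bicarbonate, 18 genes in wild type and 3 in the knockout compare with at most 2 in the other of 35 splits each. In both, 1 split of 35 (the real one) gave as many, the smallest share that 35 splits can show. This argues against chance for the 18 genes of the full set in wild type. For the knockout, chance is not excluded, as its 3 genes lie close to 2. The 14 false calls of the simulation came beside 100 changed genes per fold size. They do not tell how many false calls to expect among these 3. With single libraries left out the counts were 2 to 82 in wild type and 2 to 4 in the knockout, and other splits of the full set reach 2. The interaction gave 2 genes against up to 3 in other splits, with 10 of 100 giving as many, so chance cannot be excluded for it. For lists, the wild-type response gave 5 against up to 8 (10 of 35 splits with as many), so chance cannot be excluded. The same holds for the genotype difference on bicarbonate, with 1 against up to 6 (31 of 35). On water the genotype difference gave 0 lists against up to 7. Every split gives at least 0 lists, so this count cannot test chance. The 6 lists of the knockout response compare with at most 5 in the other splits (1 of 35 with as many, the real one). The 8 lists of the interaction compare with up to 9 (4 of 100 with as many). Few splits gave as many, but others came close to the first count and exceeded the second. With an estimated correlation 0 lists of either are called, and 0 by fry, so chance is not excluded for them. Without IRR knockout water replicate 3 or bicarbonate replicate 3, 2 and 3 lists of the knockout response were called, numbers that other splits of the full set reach.

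The interaction test was passed by Sh3bp5l (adjusted p = 0.0471) and Gm5096 (adjusted p = 0.000697), a count for which chance cannot be excluded, and by 8 lists. The lists were haemoglobin (0.000758), fasting and PPAR alpha targets (0.00115), type A intercalated cells and cell cycle (both 0.0144), tubule injury (0.0167), V-ATPase and shared genes (0.0179), interferon response (0.0217) and insulin and IGF signalling (0.0397), of which 0 hold with an estimated correlation.

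The mitochondrially encoded genes, 13 of 13 higher in the knockout libraries on both drinks but not with quantile normalization, form the first pattern. More mitochondria or more proximal tubule in the knockout slices could raise them, but 24 nuclear genes for mitochondrial proteins had a median log2 difference on water of -0.083 (quartiles -0.36 and 0.03), which argues against it. A trend with transcript length and GC content is argued against for 11 of the genes, which kept a median of 1.01 with the trend removed. These 11 were set apart from the other 2 after the values were seen. All 13 had a median of 0.99 on water with the trend removed. For mt-Atp8 and mt-Nd4l the log2 differences on water went from 1.21 (SE 0.06) and 0.55 (SE 0.08) to -0.31 (SE 0.11) and -0.57 (SE 0.14), and the highest on either drink was 0.10, so for these genes the trend stays open, as the trend at their lengths rests on the 34 tested genes of 500 nt or less. A batch that follows the genotype cannot be told apart from an effect of the knockout, since the labels give no batch and the genotypes lie 45.6 apart on the first principal component.

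The second pattern is 22 genes that differ by over 8-fold between genotypes on both drinks, 12 higher and 10 lower in the knockout. Reads shared with an overlapping gene or a near-identical copy may explain part of it, since 9 of the 22 (40.9%) have one against 13 of 500 other genes (2.6%), an odds ratio of 25.4 (95% interval 8.10 to 79.2, Fisher's exact test p = 2.47e-08). The 500 genes were drawn at random and not matched for libraries at 0. Most of the 22 genes hold such a library, against 470 of all 12943 genes tested. The odds ratio cannot tell the pattern from this difference. On water, the copies Hist2h2aa1 and Hist2h2aa2 summed to 33.8 ± 3.53 RPKM in wild type and 27.4 ± 4.81 RPKM in the knockout (SD, n = 4 each), while Eno1 and Eno1b summed to 398 ± 61.4 and 549 ± 76.1 RPKM on water and to 518 ± 122 and 504 ± 25.1 RPKM on bicarbonate, so an exchange of reads between the copies stays open. A haplotype around Insrr is argued against for the 20 genes on other chromosomes than 3, and stays open on chromosome 3, where 1 of 2 lies within 10 Mb. A batch that follows the genotype and an effect of the knockout also stay open.

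The third pattern is the fall of Slc13a3, Enpp6, Slc22a8 and Slc22a6 after bicarbonate in the average of both genotypes, with log2 changes of -0.62, -0.55, -0.26 and -0.40. Less proximal tubule in the bicarbonate slices could lower them. The 16 proximal tubule markers include Slc13a3, Slc22a8 and Slc22a6, so these genes are in part compared with themselves. Of these markers, 12 had negative changes, with a median of -0.20 (quartiles -0.36 and -0.031). This median argues against less proximal tubule as the whole cause for Slc13a3 and, by a small margin, Enpp6. It lies above their changes by more than the interquartile range of 0.33. For Slc22a8 and Slc22a6, whose changes lie near these quartiles, less proximal tubule stays open. With the length and GC trend removed, the 4 genes kept their calls and the smallest change was -0.29, which argues against that trend. An effect of the alkali load stays open as a hypothesis.

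Of 592 groups of 4 libraries examined, 48 held a library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 29.6. The most in a single library was 7. These values, in RPKM with the range of the other libraries of the group, are given by library.

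IRR knockout bicarbonate replicate 1 stood apart for Slc26a4 (17.8, others 15.0 to 15.1), Zfp52 (2.62, others at 0), Zfp930 (0.706, others at 0), mt-Nd5 (16160.3, others 17937 to 18311) and mt-Nd6 (58189, others 63091 to 63538). IRR knockout bicarbonate replicate 2 stood apart for Knstrn (0.448, others 0.178 to 0.210), Dusp1 (22.2, others 15.2 to 16.2), Hist1h2ap (2.33, others at 0), Nr3c1 (16.3, others 18.1 to 18.4), Mob2 (1.91, others at 0) and Slc7a8 (80.6, others 84.7 to 85.5). IRR knockout bicarbonate replicate 3 stood apart for Slc6a20b (49.8, others 58.2 to 59.5). IRR knockout bicarbonate replicate 4 stood apart for Atp2b4 (73.7, others 89.5 to 91.0), Cct3 (39.0, others 43.4 to 44.1), Fdps (3.68, others 7.63 to 8.11), Wnk4 (74.8, others 96.0 to 98.8), mt-Atp8 (1.31e+06, others 1.50e+06 to 1.53e+06), mt-Co3 (49813, others 57256 to 58881) and Slc22a22 (13.6, others 15.9 to 16.4). IRR knockout water replicate 1 stood apart for Hmx2 (3.04, others 3.60 to 3.68), Knstrn (0.589, others 0.941 to 1.005), Slc6a6 (102, others 118 to 121), Ermard (0.437, others at 0), Isg15 (4.88, others 2.15 to 2.31), mt-Cytb (48216, others 55104 to 56327) and Fam20a (2.12, others 1.62 to 1.65). IRR knockout water replicate 2 stood apart for Hist1h2ap (1.69, others at 0) and Maz (0, others 4.93 to 6.63). IRR knockout water replicate 4 stood apart for Slc22a8 (234, others 259 to 262) and Mrpl42 (0, others 39.3 to 59.1). Wild-type bicarbonate replicate 1 stood apart for Slc13a3 (149, others 169 to 171), Eno1b (4.00, others at 0), Hsd3b4 (20.8, others at 0), Hist2h2aa2 (9.01, others at 0), Mrpl42 (1.96, others at 0) and Klhl3 (10.6, others 12.4 to 12.7). Wild-type bicarbonate replicate 3 stood apart for Slc5a3 (31.4, others 47.6 to 50.5) and Kap (742, others 7148 to 9256). Wild-type bicarbonate replicate 4 stood apart for Knstrn (2.25, others 1.24 to 1.34), D3Ertd254e (0, others 2.16 to 2.76), Wnk4 (44.0, others 58.2 to 58.9), Sco2 (0.950, others at 0) and Acsl1 (179.8, others 247 to 254). Wild-type water replicate 1 stood apart for Fxyd2 (363, others 413 to 421) and Kcnj10 (16.7, others 19.9 to 20.4). Wild-type water replicate 2 stood apart for Per1 (13.4, others 16.2 to 16.7). Wild-type water replicate 3 stood apart for Zfp1 (2.07, others at 0). Wild-type water replicate 4 stood apart for Ermard (0, others 6.45 to 7.03).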

How the results depend on the processing

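The tests with the length and GC trend removed, with only genes above 0, with median-of-ratios scaling or single libraries left out for the lists, and all those of the averaged response and of the agreement between comparisons were chosen only after the result was seen. Across the named genes, 4603 values kept their direction and their side of the threshold, 391 lost the threshold, 16 gained it, 37 changed sign and 6 became 0 up to rounding. No scaling moved the median of all genes by over 0.1 on the log2 scale. Where a value differs below, the cause was not tested, unless the setting itself shows it.

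The 18 genes of the wild-type response to bicarbonate became 34 with quantile normalization, 5 with only the groups compared, 2 with the replicate number as a block, 10 with the length and GC trend removed, 92 at an adjusted p threshold of 0.1, and 2 to 82 with single libraries left out. The replicate numbers did not pair the animals, with a mean residual correlation of 0.0146 between libraries of the same number, and 6 of 16 libraries correlated best with their own number. With this block, 13 of the 14 named genes of the wild-type response had adjusted p from 0.0604 to 0.0824, and in the interaction Sh3bp5l had 0.0924 and Acp2 0.0347. The 3 genes of the knockout response became 2 to 4 with single libraries left out. The genotype differences gave 2245 to 2566 genes on water and 1748 to 2243 on bicarbonate with single libraries left out. With the length and GC trend removed, 8 of 83 named genes called on water lost their calls, at adjusted p from 0.0541 to 0.635. On bicarbonate 7 of 82 lost theirs, at adjusted p from 0.0742 to 0.867. The 2 interaction genes became 0 with a pseudocount of 0.01 and with a mean RPKM of at least 1, 1 with a pseudocount of 1 and with array weights, 4 without trend or robust fitting and at a threshold of 0.1, and 1 to 5 with single libraries left out. The 57 genes of the averaged response became 36 without trend or robust fitting, 29 with the replicate block, 103 at a threshold of 0.1 and 17 to 95 with single libraries left out.

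With an estimated correlation 0 lists were called in each comparison. With single libraries left out, 3 to 7 lists were called for bicarbonate in wild type, 2 to 6 in the knockout, 0 for genotype on water, 0 to 4 on bicarbonate and 6 to 9 for the interaction. The 1 list of the genotype difference on bicarbonate became 3 with quantile normalization and median-of-ratios scaling, and 2 with the replicate block and the trend removed. The correlation of the genotype differences across genes was 0.569 with a pseudocount of 0.01, 0.704 with a pseudocount of 1, and 0.585 to 0.632 with single libraries left out. That of the bicarbonate responses was -0.0144 to 0.0531 and that of the comparisons sharing wild-type water libraries 0.341 to 0.452. Insrr kept its sign, at -0.78 to -0.63 on water and -0.58 to -0.37 on bicarbonate.

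Of the 37 changes of sign, 25 were in genes that did not pass before or after. With the length and GC trend removed, Hmx2 (-0.0105) and Oxgr1 (0.0251) in the wild-type response and Adgrf5 (-0.0292) in the knockout response changed sign, and with array weights Slc4a1 (-0.0151) for genotype on water. With single libraries left out, the log2 values ran from -0.10 to 0.16 for Hmx2, -0.0784 to 0.32 for Kit and -0.20 to 0.10 for Oxgr1 in the wild-type response. They ran from -0.0447 to 0.12 for Adgrf5, -0.24 to 0.0572 for Dmrt2 and -0.0518 to 0.0455 for Insrr in the knockout response. For genotype they ran from -0.14 to 0.16 for Slc4a1 and -0.0221 to 0.23 for Slc4a8 on water, and from -0.0593 to 0.23 for Kit and -0.12 to 0.18 for Oxgr1 on bicarbonate.

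The other 12, and the 6 values that became 0, were of mitochondrially encoded genes. Quantile normalization gives the highest ranks the same value in each library, and the genotype difference on water became -0.0899 for mt-Nd1, -0.0947 for mt-Co1, -0.00857 for mt-Co2, -0.46 for mt-Co3, -0.0395 for mt-Cytb and 0 for mt-Atp8, mt-Nd4l and, up to rounding (3.55e-15), mt-Nd4. On bicarbonate it became -0.0300 for mt-Nd1, -0.0318 for mt-Nd4, -0.0791 for mt-Co1, -0.46 for mt-Co3, -0.16 for mt-Cytb and 0 for mt-Atp8, mt-Atp6 and mt-Nd4l. With the length and GC trend removed, mt-Atp8 became -0.31 and mt-Nd4l -0.57 on water. The depth of the libraries is unknown, so what it limits was not measured.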

Other observations

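All tests in this part were chosen only after the result was seen. Averaged over both genotypes, 46 genes fell and 11 rose after bicarbonate, and those given here were chosen after their values were seen. Slc13a3 changed by -0.62 ± 0.06 on the log2 scale (SE, limma adjusted p = 0.000314) and Enpp6 by -0.55 ± 0.06 (adjusted p = 0.00177). The flavin monooxygenase Fmo1 stood at -0.52, the cholesterol synthesis enzyme Hmgcs1 at -0.48, the scaffold Pdzk1 at -0.33 and Slc22a8 at -0.26, with adjusted p from 0.00920 to 0.0168. These 6 calls held with each library left out, and that of Slc22a8 was lost with quantile normalization (adjusted p = 0.0962). Slc22a6 stood at -0.40 (adjusted p = 0.0174), and lost its call without wild-type bicarbonate replicate 2 (adjusted p = 0.0514).

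At an unadjusted p under 0.05 there were 1463 genes. Of the 57 called, 54 had the same sign in both genotypes, which the choice of genes by the average of both responses favours. Over all genes tested, the 2 responses correlated with a Pearson r of 0.0224. Of 100 splits of the libraries within genotypes, 1 (the real one) gave as many as 57 genes. The highest of the others was 2, which argues against chance for the count. Chance is not excluded, since the contrast was chosen after seeing the data and 1 of 100 is the smallest share these splits can show. The count was 32, 36 and 33 without wild-type water replicates 2, 3 and 4, and 28, 17 and 95 without wild-type bicarbonate replicates 1, 2 and 4. It was 28, 25 and 37 without IRR knockout water replicates 2, 3 and 4, and 30, 19 and 19 without IRR knockout bicarbonate replicates 2, 3 and 4. By camera 4 lists were called, proximal tubule markers (adjusted p = 3.58e-05), interferon response (0.00894) and ammoniagenesis and gluconeogenesis (0.0116) lower and fasting and PPAR alpha targets (0.00202) higher, at adjusted p = 0.125, 0.307, 0.579 and 0.639 with an estimated correlation.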
